A study of Caenorhabditis elegans with 6 samples.

How the data were processed

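RNA from starved L1 larvae of wild type and lin-35(n745) C. elegans was profiled on a one-colour Affymetrix expression array, with 3 arrays per genotype. Per the labels' protocols, larvae were held 30 h at 20 °C in buffer without food, and biotin-labelled cRNA was made from 6 µg of total RNA per array. The labels name the arrays of a genotype biological replicates, so p-values measure the spread between separate samples of each genotype.

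The authors deposited log2 expression values, 1 per probe set and array, and the submitters' processing notes name RMA, with no version. RMA corrects background, normalises quantiles between arrays and summarises the probes of each probe set. It pulls the arrays' distributions together, so a change of all transcripts in 1 direction would be hidden, and it lifts dim probe sets to a floor, which understates their fold changes. The RMA software version and any filter applied before deposit are not given in the sources used here, and no detection calls were used. A dim value can therefore be background rather than expression.

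The table held 22625 probe sets. The 77 control probe sets were left out of all tests, and 22548 were tested with no further filter or normalization. Gene names came from the platform annotation, which can be old, and symbols were checked through Entrez identifiers against a WBcel235 gene table, which changed 0 of them. A single symbol was given for 20766 probe sets, several for 887 and none for 895. No gene was named from a probe set with several symbols. The 17118 genes were each represented by their brightest single-symbol probe set over all 6 arrays, and 2981 genes had more than 1. Of these, 384 had some but not all probe sets called, among them efl-1, drh-1, col-109, cdh-1 and ins-24, each with 1 of 2 called. Probe sets that can match several transcripts, marked as such in their identifiers, were kept, and an alternative left them out. No genome coordinates are reported, and the gene table served only for names and for which genes neighbour each other.

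Genotypes were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, lin-35(n745) minus wild type, with Benjamini-Hochberg adjustment over all 22548 probe sets and a threshold of 0.05 on the adjusted p. A gene or probe set is called, and said to rise or fall, when it passes that threshold. Differences are in log2 units, with limma's standard error (SE), and a difference of 1 is 2-fold. The fit had 4 residual degrees of freedom per probe set and 3.24 from the prior.

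Before the data were examined, 41 gene lists were fixed, covering the DREAM complex, germline, cell cycle, RNA interference, insulin and DAF-16 signalling, metabolism, stress, immunity, the cuticle and markers of tissues, embryos, oocytes and sperm. Each was tested with camera at a preset correlation between genes of 0.01, adjusted over the 41 lists, and again with an estimated correlation. Members called over all probe sets were counted, as were those passing when adjusted over the list alone. fry tested each list in a direction and in either direction. Some lists share members: icl-1 is in the DAF-16 and carbohydrate lists, and some embryo markers also act in the germline. The genes named in the text were also set by a rule fixed beforehand. They are lin-35, the 10 highest and 10 lowest called genes whose groups did not overlap, from each list up to 3 called members of smallest p in the direction with more calls and 1 in the other, and these anchor genes whether or not they passed: lin-9, efl-1, pgl-1, pgl-3, cye-1, rnr-1, pcn-1, rad-51, sid-1, daf-2, daf-16, sod-3, mtl-1, hsp-12.6, hsp-16.2, icl-1, lipl-4, daf-28, vit-2, ges-1, unc-54 and dpy-7. For a list without a called member, its member of smallest p could be given. Of the 144 genes this rule gave, 132 were called, and 80 of those kept the call without any 1 of the arrays. Genes of families in the closing section were chosen after their values were seen.

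The alternatives fixed beforehand were median centring of arrays, repeated quantile normalization, cyclic loess, leaving out probe sets with a mean below the 25th or 50th percentile, leaving out probe sets that can match several transcripts, the replicate number as a block, eBayes with trend and robust settings, array weights, ordinary unmoderated statistics, a floor at the 10th percentile, leaving out each array in turn, limma's treat with a fold of 1.5, and for lists an estimated correlation, fry, and the mean of a gene's probe sets. After seeing the data 3 more were added: leaving out mutant replicates 1 and 3 together, leaving out wild-type replicate 2 and mutant replicate 1 together, and the 3' to 5' difference of actin and Gapdh control probe sets as a covariate.

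The fit was tested on simulated data drawn from a normal distribution with each probe set's mean and moderated variance, and 200 changed probe sets among 22548. It recovered 5.97% of the 1.5-fold, 26.9% of the 2-fold and 93.9% of the 4-fold changes, with 6 false calls. When the simulated changes had the number and sizes of the observed calls, 85.7% of 2542 were recovered with 102 false calls. With the DNA replication list shifted by 1 in simulated data, its median was 1.05 and 0 other lists were called. The draws were set by each probe set's mean and variance, so they do not test lists whose genes vary together.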

Results

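Gene expression was measured in starved first-stage (L1) larvae of the nematode Caenorhabditis elegans on a one-colour Affymetrix array. The larvae were wild type or carried lin-35(n745), a nonsense allele of the worm's retinoblastoma (Rb) homologue. LIN-35 acts as a transcriptional repressor in the DREAM complex together with E2F and DP proteins. L1 larvae that hatch without food arrest development and survive on stored nutrients, and here they had been kept without food for 30 h at 20 °C. Each genotype was represented by 3 arrays, which the labels call biological replicates. The comparison asks which transcripts differ between the starved mutant and the starved wild type. The series holds no fed larvae, so every difference below is a difference between genotypes within starvation. Values are log2 expression after robust multi-array averaging (RMA), and array medians lay between 5.91 and 6.11. With 3 arrays per genotype, the number of arrays limits the precision.

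The lin-35 transcript did not differ detectably between genotypes. Its brighter probe set read 7.36 ± 0.19 (SD, n = 3) in the wild type and 7.42 ± 0.25 (SD, n = 3) in the mutant, a log2 difference of 0.06 with a standard error of 0.19 (limma, adjusted p = 0.894). The sign of this difference turned with median centring, repeated quantile normalization or array weights, and without wild-type replicate 2 (−0.04) or mutant replicate 1 (−0.07), and it was called in none of these. The other lin-35 probe set differed by 0.13 (limma, adjusted p = 0.803). The allele is a point mutation that leaves the probed sequence in place, so these probe sets do not check the genotype labels. Genotype separated the arrays on the leading principal component, which carried 59.1% of the variance. Correlations between arrays of the same genotype averaged 0.975 to 0.985 per array, across probe sets.

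Expression differed between genotypes in 2542 of 22548 probe sets, 11.3% of those tested. Of these, 1282 were higher and 1260 were lower in lin-35(n745). Large changes were mostly increases: 307 probe sets were at least 4-fold higher and 62 at least 4-fold lower, while 987 were at least 2-fold higher and 747 at least 2-fold lower. By the brightest probe set of each gene, 978 genes were higher and 1047 lower out of 17118 measured, so that 11.8% were called. Genes called on a dimmer probe set alone are not in these counts. No gene had called probe sets in opposite directions. In all 2542 the mutant arrays lay entirely above or entirely below the wild-type arrays, as did 30.5% of all probe sets, where chance alone gives 10%. Centring each array on its median moved the median log2 difference of all probe sets from −0.03 to −0.11 and the share of higher calls from 50.4% to 37.6%, with 2117 lower calls. Leaving out wild-type replicate 1 gave 1002 calls, wild-type replicate 2 gave 1371 and mutant replicate 3 gave 1578.

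The 3' to 5' differences of control transcripts, a measure of RNA quality, varied between arrays. The log2 difference between the 3' and 5' probe sets of the actin control transcript was 0.53, 0.70 and 0.78 on wild-type replicates 1 to 3, and 2.31, 0.41 and 1.23 on mutant replicates 1 to 3. For actin, mutant replicate 2 thus lay below the wild-type range, and mutant replicates 1 and 3 lay above it. For catalase mutant replicate 1 alone lay above it, at 3.73, and mutant replicate 3, at 1.55, lay within it. With mutant replicates 1 and 3 both left out, an alternative chosen after seeing the data, 583 probe sets were higher and 185 were lower. That fit has a lone mutant array, which is assumed to vary like the wild-type arrays.

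**Figure D1:**
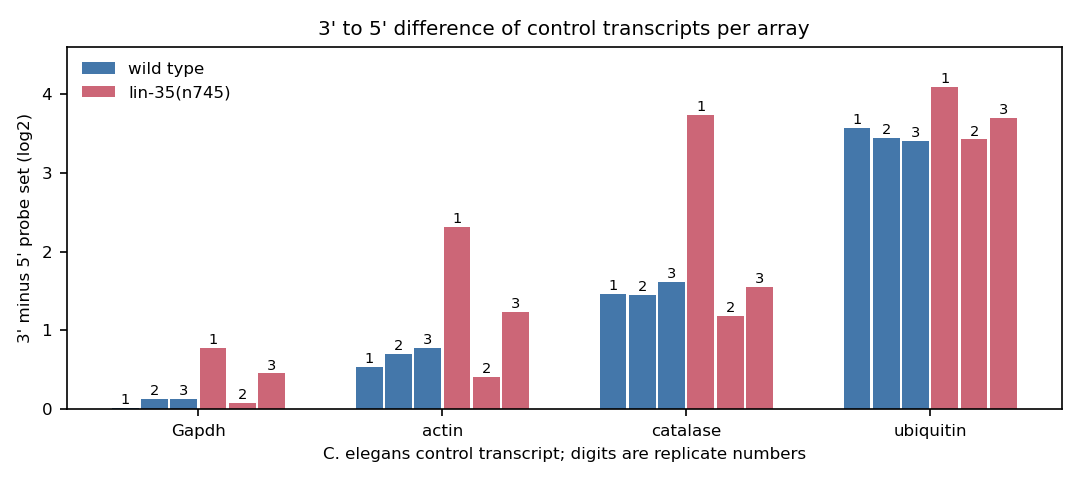
Log2 difference between the 3' and 5' probe sets of 4 C. elegans control transcripts, a bar per array, with wild type in blue, lin-35(n745) in red and the replicate number above each bar. For actin, mutant replicates 1 and 3 (2.31 and 1.23) stood above the wild-type arrays (0.53 to 0.78) and mutant replicate 2 (0.41) below them.

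The highest fold change belonged to C06B3.7, which rose from 3.68 ± 0.23 to 9.33 ± 0.80 (SD, n = 3), a log2 difference of 5.66 (SE 0.38, limma adjusted p = 0.000448). Next came ugt-29 at 5.52 (SE 0.28, adjusted p = 0.000135), a UDP-glucuronosyltransferase of xenobiotic conjugation, and tbb-6 at 5.26 (SE 0.27, adjusted p = 0.000135), a beta-tubulin. The others among the 10 highest were F37D6.3 (5.14), nspe-7 (5.03), hpo-32 (4.87), Y58A7A.4 (4.84), ugt-26 (4.78), Y58A7A.3 (4.77) and Y38E10A.14 (4.64), with adjusted p between 9.62e-05 and 0.00342. Several of these, among them nspe-7, Y58A7A.3 and Y58A7A.4, were measured by probe sets that can match more than 1 transcript. The lowest fold change was that of dod-24, which fell from 10.5 ± 0.51 to 6.17 ± 0.30 (SD, n = 3), a log2 difference of −4.31 (SE 0.29, adjusted p = 0.000427). It was followed by the cathepsin B-like protease gene cpr-2 at −4.06 (SE 0.29, adjusted p = 0.000552) and the C-type lectin gene clec-52 at −3.53 (SE 0.28, adjusted p = 0.000749). The putative enoyl-CoA hydratase gene ech-7 stood at −2.77 (adjusted p = 0.00146) and Y97E10AL.1 at −2.77 (adjusted p = 0.00849). All of the genes named so far in this paragraph kept their calls without any 1 of the 6 arrays. The cuticle collagen gene dpy-5 (−3.41, adjusted p = 0.0194) lost its call without wild-type replicate 1 (0.0549) and without mutant replicate 3 (0.0788), in a range of 0.00565 to 0.26 over all alternatives. Likewise txt-4 (−2.99, adjusted p = 0.0188) lost its call without wild-type replicate 1 (0.0727), wild-type replicate 2 (0.0548) and mutant replicate 3 (0.0823), in a range of 0.00167 to 0.146. The remaining 3 of the 10 lowest, lips-15 (−2.87), gst-41 (−2.78) and flp-3 (−2.63), each lost the call when any of several arrays was left out. Without mutant replicate 3, for example, their adjusted p was 0.124, 0.0887 and 0.147, and without wild-type replicate 1 it was 0.063, 0.0794 and 0.138. Without wild-type replicate 2 it was 0.12, 0.0636 and 0.133, and without mutant replicate 1 it was 0.0541, 0.0607 and 0.0973. For lips-15 it was also 0.0891 without wild-type replicate 3. Over all alternatives their adjusted p ranged up to 0.276, 0.298 and 0.423 in that order.

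Genes of DNA replication and mitosis were higher in starved lin-35(n745) larvae. Of 60 mitotic genes, 40 rose and none fell, with a median log2 difference of 1.57 and 43 higher when adjusted over the list alone (camera, adjusted p = 5.07e-28). They included hcp-6, a condensin subunit, at 3.09 (SE 0.20, limma adjusted p = 0.000427), cyk-4, a cytokinesis protein, at 2.71 (SE 0.19, adjusted p = 0.000552), and sep-1, the separase that frees sister chromatids, at 2.33 (SE 0.14, adjusted p = 0.000297). Of 40 replication genes, 25 rose and none fell, with a median of 1.302, and adjusted over the list alone 31 were higher and 1 lower (camera, adjusted p = 1.07e-19). The licensing regulator cdt-2 stood at 2.85 (SE 0.15, adjusted p = 0.000145), topoisomerase II top-2 at 2.07 and the polymerase alpha subunit div-1 at 1.94. Ribonucleotide reductase rnr-1 was higher by 1.54 (SE 0.21, adjusted p = 0.00584), while the sliding clamp pcn-1 differed by 1.11 without passing the threshold (adjusted p = 0.088), which it passed with the 3' to 5' covariate alone among the alternatives. Among 42 DNA repair genes 16 rose and 1, ercc-1, fell, with a median of 0.71, and 21 were higher and 1 lower adjusted over the list alone (camera, adjusted p = 2.81e-10). The mismatch repair gene msh-6 (2.69), the double-strand break nuclease mre-11 (2.80) and the BRCA1 homologue brc-1 (2.09) were among those that rose. The call of ercc-1, at −0.92 (adjusted p = 0.0185), was lost without wild-type replicate 1 (0.0841), wild-type replicate 3 (0.0596) or mutant replicate 3 (0.056). Of 16 regulators of the G1 to S step 4 rose and none fell, with a median of 0.45, and 5 were higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.00159). They included cyclin E cye-1 at 2.57 (SE 0.22, adjusted p = 0.00091), the Cdk inhibitor cki-2 at 1.55 and the Cdk1-inhibiting kinase wee-1.3 at 1.77. With an estimated correlation between genes these 4 list calls were lost: adjusted p was 0.442 for mitosis and for replication, and 0.458 for repair and for G1 to S. With mutant replicate 2 as the lone mutant array 18 mitotic, 15 replication, 10 repair and 1 G1 to S genes were higher.

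**Figure D2:**
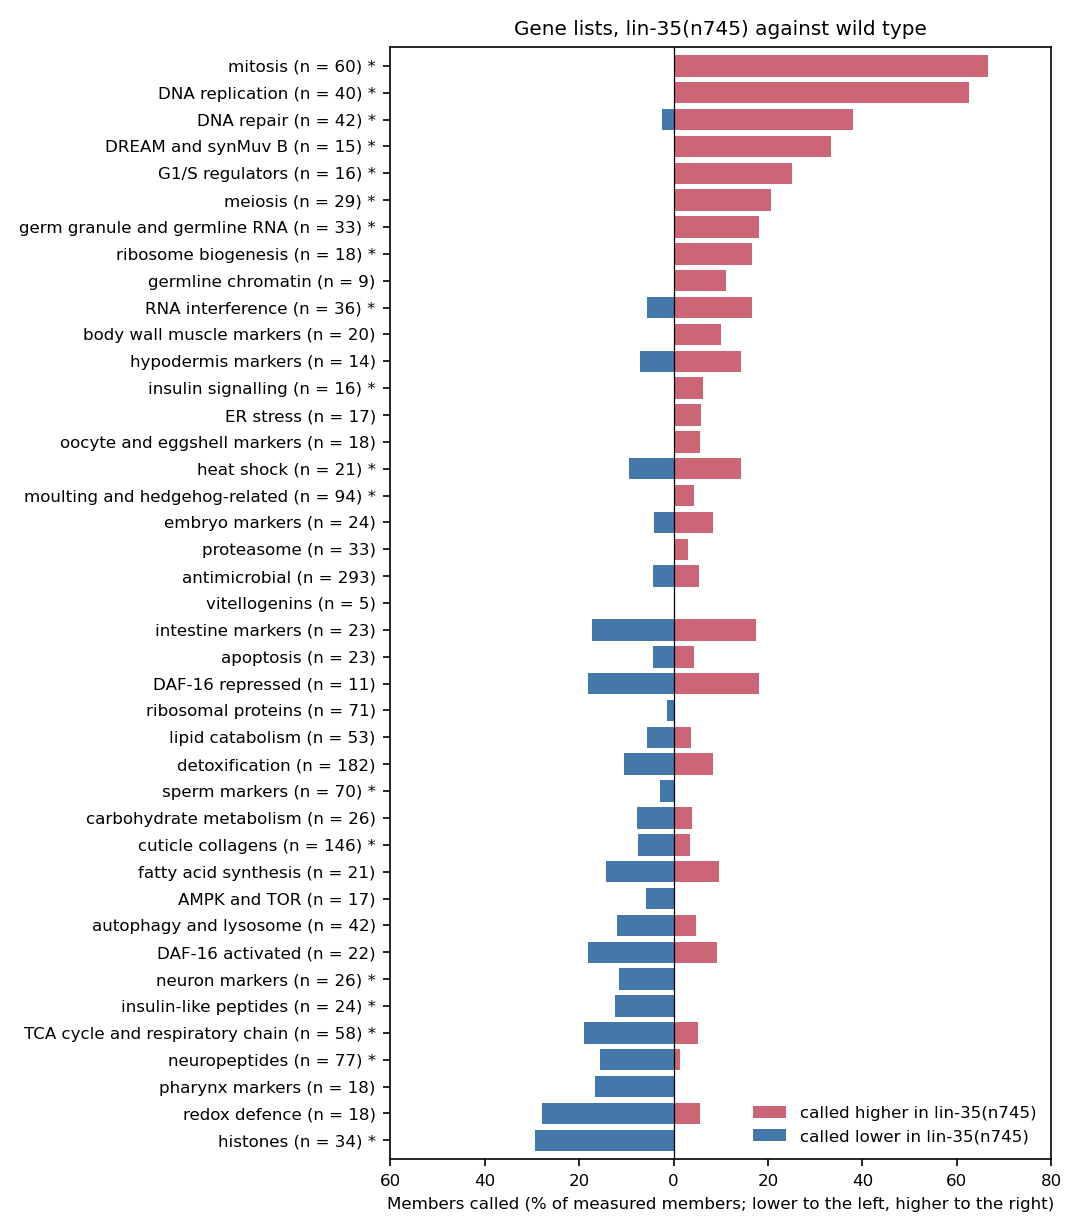
Share of each gene list's measured members called higher (red, to the right) and lower (blue, to the left) in lin-35(n745), in percent, with an asterisk where camera's adjusted p with the preset correlation was below 0.05. Mitosis (40 of 60 members higher) and DNA replication (25 of 40) lead the increases, and histones (10 of 34 lower) the decreases.

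A minority of germline genes were also higher in the mutant. Of 33 germ granule and germline RNA genes 6 rose and none fell, with 6 higher and 1 lower adjusted over the list alone and a median of 0.14 (camera, adjusted p = 0.00341, and 0.458 with an estimated correlation). The germline helicase glh-1 rose from 5.89 ± 0.63 to 10.3 ± 0.36 (SD, n = 3), a log2 difference of 4.40 (SE 0.34, limma adjusted p = 0.000733). The P granule proteins pgl-3 and pgl-1 were higher by 3.42 (SE 0.18, adjusted p = 0.000161) and 2.66 (SE 0.22, adjusted p = 0.000836). The list call was lost without wild-type replicate 2 (adjusted p = 0.0856), and over the alternatives ranged from 0.000682 to 0.458. Of 29 meiotic genes 6 rose and none fell, with 6 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.0102, and 0.442 with an estimated correlation). The meiotic median of 0.07 turned to −0.02 when arrays were centred on their medians, so the list moved through a minority of its members. The synaptonemal complex gene syp-1 was higher by 4.62 (SE 0.21, adjusted p = 0.000128), the meiotic axis gene him-3 by 1.89 (SE 0.15), the cohesin subunit coh-3 by 1.92 (SE 0.24) and the recombinase rad-51 by 1.70 (SE 0.23, adjusted p = 0.00602). Among 9 germline chromatin genes the histone methyltransferase mes-4 alone was called, at 2.66 (SE 0.26, adjusted p = 0.00179), and 2 were higher and 1 lower adjusted over the list alone (list median 0.22, camera adjusted p = 0.228). Markers of unhatched embryos, oocytes and eggshell, or sperm were tested beside these genes. Of 24 embryo markers 2 rose, including the Notch receptor glp-1 (0.98), which also acts in the germline, and 1 fell, with the same counts adjusted over the list alone (median 0.02, camera adjusted p = 0.311), the sign of the median turning with median centring and with repeated quantile normalization. The higher embryo count was 1 without any 1 array but mutant replicate 1, and the lower count 0 without wild-type replicate 1 or 3 or mutant replicate 2 or 3. Without wild-type replicate 1 the embryo list was called higher, with a median of 0.23 (adjusted p = 0.0318, range over the alternatives 0.0318 to 0.906). Of 18 oocyte and eggshell markers 1 rose (0 adjusted over the list alone), with a median of −0.15 although the test pointed upwards (adjusted p = 0.525), and the count was 0 without wild-type replicate 2 or 3 or mutant replicate 1 or 3. Of 70 sperm markers 2 fell and none rose (0 adjusted over the list alone, median −0.17, camera adjusted p = 0.0323, and 0.782 with an estimated correlation). The sperm list's call was lost without wild-type replicate 2 (0.166), mutant replicate 1 (0.144) or mutant replicate 2 (0.241), in a range of 0.000745 to 0.782, and its count was 0 without any 1 array but wild-type replicate 3. Other lists hold 3 of the embryo, 3 of the oocyte and 0 of the sperm markers.

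**Figure D3:**
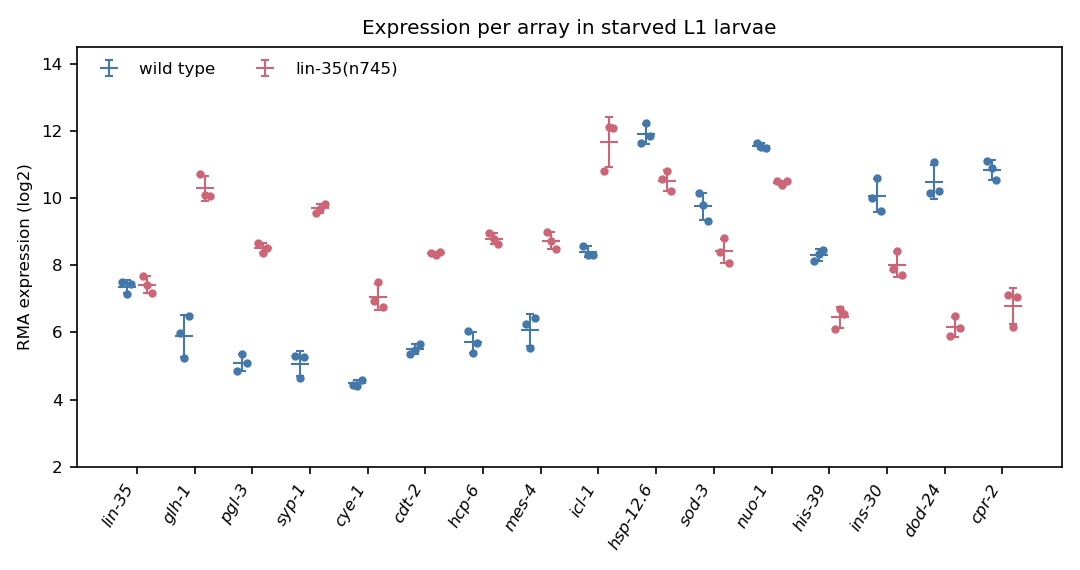
RMA expression (log2 units) of 16 genes on each array, with wild type in blue and lin-35(n745) in red, where points are arrays, horizontal marks are means and vertical bars are SDs (n = 3 per group). The groups overlap for lin-35 (7.36 and 7.42), while glh-1 rose from 5.89 to 10.3 and dod-24 fell from 10.5 to 6.17.

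LIN-35's own partners were among the genes that rose. Of 15 DREAM and synMuv B genes 5 were higher and none lower, with a median of 0.76 and 9 higher adjusted over the list alone (camera, adjusted p = 0.000115, and 0.458 with an estimated correlation). The DREAM subunit lin-9 was higher by 2.01 (SE 0.17, limma adjusted p = 0.00105), the E2F gene efl-1 by 1.84 (SE 0.29, adjusted p = 0.00908) and the DP gene dpl-1 by 1.99 (SE 0.33, adjusted p = 0.0113). For efl-1, 1 of its 2 probe sets was called. Without wild-type replicate 1, mutant replicate 2 or mutant replicate 3 the count was 3 of 15. With probe sets that can match several transcripts left out, 5 members remained measured and the adjusted p was 0.202. Of 36 RNA interference genes 6 rose and 2 fell (9 and 3 adjusted over the list alone, median 0.13), with rde-4 at 2.39 (SE 0.21, adjusted p = 0.00122), a double-stranded RNA binding protein, the helicase drh-1 at 1.34 and rrf-2 at 1.92. The list test (camera, adjusted p = 0.0345, and 0.777 with an estimated correlation) was lost without wild-type replicate 2 (0.384) or mutant replicate 1 (0.174), with repeated quantile normalization (0.0685), with mutant replicate 2 as the lone mutant array (0.271), with the 3' to 5' covariate (0.174) and in other alternatives, in a range of 0.00164 to 0.777. The lower count was 0 without wild-type replicate 1, wild-type replicate 3 or mutant replicate 2 and 1 without wild-type replicate 2 or mutant replicate 3. The double-stranded RNA importer sid-1 differed by 0.71 (adjusted p = 0.0775) and passed the threshold with array weights alone among the alternatives. Of 18 ribosome biogenesis genes 3 were called higher and none lower, also adjusted over the list alone, with a median of 0.62 (camera, adjusted p = 0.00159, and 0.458 with an estimated correlation). That count fell to 0 without wild-type replicate 2, mutant replicate 2 or mutant replicate 3, and to 1 without wild-type replicate 1 or mutant replicate 1, while the list test stayed below 0.05.

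Targets of the starvation-active transcription factor DAF-16 moved both ways. Of 22 genes known to rise with DAF-16, 2 were higher and 4 lower in the mutant, and 3 and 4 adjusted over the list alone (camera, adjusted p = 0.811). The list's median of −0.06 and mean of 0.18 differ in sign, and the median turned positive after repeated quantile normalization or cyclic loess. The higher count was 1 without wild-type replicate 1 or 3 or mutant replicate 2 or 3. The small heat shock genes hsp-12.6 and hsp-12.3 fell, hsp-12.6 from 11.9 ± 0.31 to 10.5 ± 0.31 (SD, n = 3; −1.39, SE 0.23, limma adjusted p = 0.0106) and hsp-12.3 by −1.13 (SE 0.16, adjusted p = 0.00611), as did dao-3 (−1.25, adjusted p = 0.00728). The glyoxylate cycle gene icl-1 rose by 3.27 (SE 0.35, adjusted p = 0.00237). The superoxide dismutase sod-3 was lower by −1.32 (SE 0.27, adjusted p = 0.0237), a call lost without wild-type replicate 1 (0.0837), wild-type replicate 2 (0.0743), mutant replicate 1 (0.0518) or mutant replicate 3 (0.078), in a range of 0.00723 to 0.257 over the alternatives. The metallothionein mtl-1 (−0.46, adjusted p = 0.565) and the lipase lipl-4 (0.13, adjusted p = 0.751) did not pass the threshold, although without mutant replicate 1 mtl-1 did (adjusted p = 0.0301). Readings of lipl-4, from 3.35 to 3.89, lie near the dim end of the array and can be background. Of 11 genes known to fall with DAF-16, 2 rose and 2 fell, and 4 and 2 adjusted over the list alone (median 0.04, negative with median centring, camera adjusted p = 0.434). The higher count was 1 without wild-type replicate 1 or 3, and the lower count 1 without wild-type replicate 1 or 2 or mutant replicate 1 or 3. In opposite directions, dod-19 rose by 3.49 (SE 0.27, adjusted p = 0.000769) and dod-24 fell as given above. In the insulin pathway upstream, the receptor daf-2 differed by 0.05 (adjusted p = 0.921), near the dim end of the array, and daf-16 by 0.73 (adjusted p = 0.0508), which passed in 5 alternatives: without mutant replicate 2 (0.0222), with repeated quantile normalization, cyclic loess or array weights, and with probe sets below the median left out (range 0.0222 to 0.652). Of 16 pathway genes 1 was called higher (2 adjusted over the list alone, median 0.12, camera adjusted p = 0.0417, and 0.724 with an estimated correlation). That list test was lost without wild-type replicate 2 (0.295), without mutant replicate 1 (0.262), with median centring (0.0582), with mutant replicate 2 as the lone mutant array (0.19) and with the 3' to 5' covariate (0.338), in a range of 0.00672 to 0.724. The count was 0 without mutant replicate 3 and 2 without mutant replicate 2. Of 24 insulin-like peptides 3 fell and none rose (10 lower and 1 higher adjusted over the list alone, median −0.34, camera adjusted p = 0.0339, and 0.724 with an estimated correlation). The peptide ins-30 was lower by −2.05 (SE 0.29, adjusted p = 0.00698), and daf-28 differed by −0.32 (adjusted p = 0.557). The list test was lost without wild-type replicate 2 (0.153) or mutant replicate 1 (0.142), with mutant replicate 2 as the lone mutant array (0.211, 0 lower) and with the 3' to 5' covariate (0.154, 2 lower), in a range of 0.00473 to 0.724. The count was 1 without wild-type replicate 1 or mutant replicate 3 and 6 without wild-type replicate 3.

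With all 6 arrays, more transcripts of mitochondrial energy metabolism were called lower than higher. Of 58 genes of the tricarboxylic acid (TCA) cycle and respiratory chain 11 fell and 3 rose, and 22 and 4 adjusted over the list alone, with a median of −0.43 (camera, adjusted p = 0.000115, and 0.458 with an estimated correlation). The complex I gene nuo-1 fell from 11.6 ± 0.08 to 10.5 ± 0.06 (SD, n = 3), by −1.09 (SE 0.14, limma adjusted p = 0.0042), and the dihydrolipoamide dehydrogenase dld-1 by −1.06 (SE 0.16, adjusted p = 0.00796). Against that direction cox-10, an assembly factor of complex IV, rose by 2.04 (SE 0.16, adjusted p = 0.000808). The balance turned without wild-type replicate 1, with 2 lower and 3 higher, and with mutant replicate 2 as the lone mutant array, with 1 lower and 2 higher. The lower count was 7 without mutant replicate 3 or with the 3' to 5' covariate. Lists of fat and sugar metabolism were not called. Of 53 lipid catabolism genes 2 rose and 3 fell (the same counts adjusted over the list alone, median 0.08, camera adjusted p = 0.291), with ech-7 lower and the peroxisomal thiolase daf-22 higher by 1.32 (SE 0.19, adjusted p = 0.00719). Of 21 fatty acid synthesis genes 2 rose and 3 fell, and 4 and 4 adjusted over the list alone (median 0.01, camera adjusted p = 0.636), with the fatty acid synthase fasn-1 higher by 1.44 (SE 0.16, adjusted p = 0.00237). Without any 1 of the wild-type replicates 1 lipid catabolism gene was lower. The lower count of fatty acid synthesis was 0 without wild-type replicate 1 or 2 and 1 without any other array, and its higher count was 1 without wild-type replicate 1. Of 26 genes of carbohydrate metabolism 1, icl-1, rose and 2 fell, also adjusted over the list alone (median −0.04, mean 0.10, camera adjusted p = 0.905). Without wild-type replicate 1 or 2 its lower count was 0. The medians of these 3 metabolic lists change sign under at least 1 of the scalings tried. Among 17 genes of AMPK and TOR signalling 1 fell, also adjusted over the list alone (median 0.13, adjusted p = 0.311), and 0 did without wild-type replicate 1, wild-type replicate 2 or mutant replicate 3. Of 71 cytoplasmic ribosomal protein genes 1, rpl-11.1, fell by −1.56 (SE 0.18, adjusted p = 0.00303), also adjusted over the list alone, while the list median of −0.07 (camera, adjusted p = 0.306) turned to 0.18 with cyclic loess (adjusted p = 0.00092, range over the alternatives 0.00092 to 0.782). fry called this list lower (adjusted p = 0.0198).

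Stress, detoxification and immunity lists held large changes in both directions. Over all 17118 genes 978 rose and 1047 fell, so that 11.8% were called. The antimicrobial, endoplasmic reticulum stress, proteasome and apoptosis lists did not exceed that share. Of 182 genes of 3 detoxification families 15 rose and 19 fell, and 17 and 24 adjusted over the list alone (median 0.01, changing sign with the scaling, camera adjusted p = 0.811). The glucuronosyltransferase ugt-31 rose by 4.47 (SE 0.19, limma adjusted p = 0.000128), whereas the glutathione S-transferases gst-20 (−1.80, SE 0.16, adjusted p = 0.00126), gst-10 (−2.41, SE 0.23) and gst-6 (4.28-fold lower) fell. Without wild-type replicate 1 the detoxification counts were 7 and 9, without wild-type replicate 2 there were 9 lower, and without mutant replicate 3 there were 12. With mutant replicate 2 as the lone mutant array they were 8 and 5. Of 18 redox defence genes 1 rose and 5 fell, also adjusted over the list alone (median −0.41, camera adjusted p = 0.311). The thioredoxin reductases parted, with cytosolic trxr-1 higher by 1.95 (SE 0.22, adjusted p = 0.00257) and mitochondrial trxr-2 lower by −1.88 (SE 0.14, adjusted p = 0.000552). The lower redox count was 1 without wild-type replicate 1 or 2, 2 without mutant replicate 3, and 3 without wild-type replicate 3 or mutant replicate 2. It was 1 with mutant replicate 2 as the lone mutant array and 2 with the 3' to 5' covariate. Of 293 antimicrobial and related genes 16 rose and 13 fell, also adjusted over the list alone (median −0.01, mean 0.01, changing sign with the scaling, adjusted p = 0.808), with irg-2 higher by 3.17 (SE 0.23, adjusted p = 0.000552), irg-1 by 3.13 (SE 0.22) and the caenacin cnc-4 by 2.65 (SE 0.26). The lower count was 7 without wild-type replicate 1 or 2, 8 without mutant replicate 3 and 3 with mutant replicate 2 as the lone mutant array. Among 21 heat shock genes 3 rose and 2 fell, and 4 and 2 adjusted over the list alone (median 0.64, camera adjusted p = 0.0282, and 0.533 with an estimated correlation). The chaperone hsp-110 rose by 1.66 (SE 0.16, adjusted p = 0.00144), while hsp-12.3 and hsp-12.6 fell. The list test was lost without wild-type replicate 2 (0.0539) or mutant replicate 2 (0.178), and the higher count was 1 without wild-type replicate 1, mutant replicate 2 or mutant replicate 3 and 5 without mutant replicate 1. The call of hsp-16.2, at 2.44 (adjusted p = 0.0373), was lost without wild-type replicate 1 (0.122), wild-type replicate 3 (0.0865), mutant replicate 2 (0.0813) or mutant replicate 3 (0.13), in a range of 0.00243 to 0.196. Of 17 endoplasmic reticulum stress genes 1 rose, and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.295, and 0.0414 with mutant replicate 2 as the lone mutant array, in a range of 0.0414 to 0.897). The higher count was 0 without any 1 of the wild-type replicates or mutant replicate 3, and 2 without mutant replicate 1. Of 33 proteasome genes 1, pas-7, rose by 1.99 (camera adjusted p = 0.811), and of 23 apoptosis genes 1 rose and 1 fell (camera adjusted p = 0.827), in both lists also adjusted over the list alone. The apoptosis counts lay between 0 and 2 in each direction over the fits without 1 array: 0 higher without any 1 of the wild-type replicates or mutant replicate 1, 2 higher without mutant replicate 2, 0 lower without wild-type replicate 1 and 2 lower without mutant replicate 1. Without mutant replicate 2 the proteasome list was called lower, with 3 lower and a median of −0.23 (adjusted p = 0.0367), and with that replicate as the lone mutant array it was called higher, with a median of 0.34 (0.000994), in a range of 0.000994 to 0.948. Of 42 autophagy and lysosome genes 2 rose and 5 fell, and 4 and 9 adjusted over the list alone (median −0.25, adjusted p = 0.311), with 0 lower without wild-type replicate 1, 1 without wild-type replicate 2, wild-type replicate 3 or mutant replicate 3, and 3 without mutant replicate 1. The higher count was 1 without wild-type replicate 1, wild-type replicate 2 or mutant replicate 3.

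Neuropeptide and histone lists leaned lower in lin-35(n745). Of 77 neuropeptide genes 12 fell and 1 rose, and 38 and 1 adjusted over the list alone, with a median of −0.64 (camera, adjusted p = 2.64e-09, and 0.533 with an estimated correlation). The higher count was 0 without any 1 of the 6 arrays. The lower count depended on the arrays: 0 without wild-type replicate 1, 1 without wild-type replicate 2 or mutant replicate 3, 4 without mutant replicate 1 and 19 without mutant replicate 2. It was 1 with the 3' to 5' covariate and 0 with mutant replicate 2 as the lone mutant array, while the list median was then −0.51 (camera, adjusted p = 6.77e-06). Of 26 neuron markers 3 fell and none rose (6 lower adjusted over the list alone, median −0.41, camera adjusted p = 0.0298, and 0.458 with an estimated correlation), among them the ciliary transport gene osm-6 by −1.33 (SE 0.20, limma adjusted p = 0.00857). That list test was lost without wild-type replicate 3 (0.0594) or mutant replicate 1 (0.0742), with repeated quantile normalization (0.0685) and cyclic loess (0.0885), with mutant replicate 2 as the lone mutant array (0.185, 0 lower) and with the 3' to 5' covariate (0.0936, 1 lower), in a range of 0.0108 to 0.458. The count was 1 without any 1 of the wild-type replicates. Of 34 histone genes 10 fell and none rose (17 lower adjusted over the list alone, median −0.54, camera adjusted p = 7.19e-06, and 0.458 with an estimated correlation), including his-39 by −1.85 (SE 0.20, adjusted p = 0.00237), his-62 by −1.72 (SE 0.22) and his-4 by −1.68 (SE 0.19). Histone genes have near-identical copies, so single members are uncertain, and with such probe sets left out 1 of 15 histone genes fell (median −0.27, camera adjusted p = 0.167). The count of 10 was 6 without any 1 of the wild-type replicates or with the 3' to 5' covariate and 3 with mutant replicate 2 as the lone mutant array. Of 146 cuticle collagens 11 fell and 5 rose, also adjusted over the list alone (median −0.24, camera adjusted p = 0.0107, and 0.724 with an estimated correlation). Those that fell included col-39 (−2.11, SE 0.30, adjusted p = 0.00685) and col-91 (−1.70, SE 0.24), and col-109 rose by 2.07 (SE 0.28). The collagen test was lost without wild-type replicate 3 (0.0739) or mutant replicate 1 (0.144) and with the 3' to 5' covariate (0.066, 4 lower), in a range of 0.000171 to 0.724. With mutant replicate 2 as the lone mutant array 2 fell and 2 rose (0.00452). The lower count was 5 without wild-type replicate 1, 6 without mutant replicate 3 and 7 without wild-type replicate 3 or mutant replicate 2. The higher count was 2 without wild-type replicate 3 and 3 without wild-type replicate 2. Without wild-type replicate 1, 3 collagens that rose lost their calls: col-48, col-113 and col-165 (limma adjusted p = 0.068, 0.0802 and 0.084). Of 94 moulting and hedgehog-related genes 4 rose and none fell (1 adjusted over the list alone, median 0.11, camera adjusted p = 0.0184, and 0.533 with an estimated correlation), with the patched-related ptr-8 at 1.29 (SE 0.17). The count was 1 without mutant replicate 2 and 2 without wild-type replicate 3. Over all genes 11.8% were called, a share that neither the collagen nor the moulting list exceeded.

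Marker lists of the other tissues were not called with all 6 arrays. Of 23 intestine markers 4 rose and 4 fell, and 6 and 6 adjusted over the list alone (median 0.21, camera adjusted p = 0.381). The intestinal actin act-5 rose by 1.65 (SE 0.17, limma adjusted p = 0.00187), and the cathepsin B-like proteases cpr-4 and cpr-5 moved apart, at 2.01 (SE 0.33, adjusted p = 0.0112) and −2.21 (SE 0.23, adjusted p = 0.00225). The gut esterase ges-1 differed by 0.39 (adjusted p = 0.145). The higher intestine count was 2 without wild-type replicate 3 or mutant replicate 3, and the lower count 1 without wild-type replicate 2 and 2 without wild-type replicate 1, wild-type replicate 3 or mutant replicate 3. Of 20 body wall muscle markers 2 rose (median −0.10, mean 0.18, changing sign with the scaling, adjusted p = 0.746), and the myosin unc-54 differed by 0.95 (adjusted p = 0.523). The muscle count was 0 without wild-type replicate 1 or 2 or mutant replicate 1 or 3, and with mutant replicate 2 as the lone mutant array or the 3' to 5' covariate. Of 18 pharynx markers 3 were called lower, although the list median was 0.26 (adjusted p = 0.893). That count was 0 without wild-type replicate 1, wild-type replicate 2 or mutant replicate 3, 5 without mutant replicate 2, and 1, with 2 higher, without mutant replicate 1. With mutant replicate 2 as the lone mutant array the pharynx list was called, with 3 higher and 0 lower (adjusted p = 0.0189, range over the alternatives 0.0189 to 0.95). Of 14 hypodermis markers 2 rose and 1 fell (median 0.26, adjusted p = 0.132), the same counts as adjusted over the list alone for all 3 of these lists, with the cadherin cdh-1 at 1.55 (SE 0.21, adjusted p = 0.00554). The higher hypodermis count was 1 without any 1 array but mutant replicate 1, and the lower count 0 without any 1 array but mutant replicate 2. Without wild-type replicate 3 the hypodermis list was called higher (adjusted p = 0.0196, range over the alternatives 0.0196 to 0.712). The hypodermal collagen dpy-7 differed by 0.54 (adjusted p = 0.406). None of the 5 vitellogenins was called (median −0.06, mean 0.05, adjusted p = 0.893, 0 also adjusted over the list alone), with vit-2 at 0.44 (adjusted p = 0.44). Mean readings of vit-2, 3.08 in the wild type and 3.52 in the mutant, lie near the dim end of the array and can be background. Across the 41 lists, camera with its preset correlation called 12 higher and 7 lower, and 11 of these 19 kept the call without any 1 of the arrays. With probe sets that can match several transcripts left out, the DREAM and histone lists lost the call as given above, and others lost it at adjusted p of 0.6 (RNA interference), 0.167 (insulin signalling and neuron markers), 0.0891 (ribosome biogenesis), 0.236 (collagens), 0.0702 (moulting), 0.0727 (heat shock) and 0.556 (sperm markers). With an estimated correlation camera called 0 of the 41 lists, and its lowest adjusted p was 0.442. Whether that setting can call a list with 6 arrays was not tested. The method fry, which tests a list on its own, called 11 in a direction and 37 when either direction counted. It does not compare a list with the other genes, and 11.8% of all genes were called. The counts from fry therefore do not set these lists apart from other genes.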

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

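The covariate fit, the fits that leave out 2 arrays together and the split of carry-over markers by kind and level were chosen after the data were seen. The control probe sets, which were left out of the tests of genotype, had a mean 3' to 5' difference over the mutant arrays above that of each wild-type array. The mean log2 difference over the mutant arrays was 1.32 for actin, against 0.67 in the wild type, and 0.44 for Gapdh, against 0.09. For catalase it was 2.16 against 1.51, and for ubiquitin 3.74 against 3.48. Mutant replicate 1 had the highest value for each of the 4 transcripts. For catalase it alone was raised, at 3.73, with mutant replicate 3 at 1.55, within the wild-type range of 1.45 to 1.62. Mutant replicate 2 lay within or below the wild-type range for each. The difference between genotypes in these control values was not tested.

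A steep 3' to 5' difference is a sign of degraded or incompletely copied RNA, which could lower transcripts on mutant replicates 1 and 3 and so add to the 1260 lower calls. If that were the whole cause, mutant replicate 2 would lie near the wild type for probe sets called lower without it. Over those 1235 probe sets its median difference from the wild-type mean was −0.79, against −1.24 for mutant replicates 1 and 3, a ratio of 0.637 (95% bootstrap interval 0.606 to 0.67), and 91.9% of them lay below all wild-type arrays. Mutant replicate 2 thus lay lower as well, by less. The interval covers the spread between probe sets, not between arrays, as mutant replicate 2 is 1 array. The probe sets were also chosen as lower against the same wild-type arrays, which can push the ratio and the 91.9% upwards. The values therefore cannot decide whether RNA quality is the whole cause, and a part of the size of the lower calls stays open to it. With the 3' to 5' difference as a covariate 753 probe sets were lower, and the same ratio was 1.0999 for the 983 probe sets called higher. The genotype itself stays open as an explanation for the lower calls.

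The germ granule and meiosis genes called higher, 12 of 62 measured with a median log2 difference of 1.95, could come from unhatched embryos or adult tissue among the mutant larvae. Such tissue would bring embryo, oocyte, eggshell and sperm transcripts with it. The 109 such markers held by no germline list had a median of −0.12 (95% bootstrap interval −0.17 to −0.05), with 3 called higher and 3 lower. The upper end of that interval lies below 0.98, the bound whose rule was set before the test. Of these markers 70 are sperm markers, which embryos would not bring (median −0.17, interval −0.20 to −0.09). The 39 embryo, oocyte and eggshell markers had a median of −0.03 (interval −0.13 to 0.21), with 18 positive. The 16 of these above the median of all values in the wild type had a median of 0.48 (interval −0.09 to 0.76), with 11 positive, 3 called higher and 0 lower. The 5 most abundant leaned upwards without passing the threshold: skn-1 read 10.1 in the wild type and 10.9 in the mutant (adjusted p = 0.175), pal-1 8.80 and 9.34 (0.273), lin-41 8.25 and 8.95 (0.151), spn-4 7.72 and 8.70 (0.106) and mex-5 7.19 and 7.82 (0.423). The next, cpg-1 and mei-1, differed by −0.20 and −0.07. The embryo list was called higher without wild-type replicate 1 (median 0.23, adjusted p = 0.0318, range over alternatives 0.0318 to 0.906). Each of these intervals ends below the bound. That bound rests on genes picked because they were called higher, while the markers were taken whether called or not. As whole lists, the germ granule and meiosis genes had medians of 0.14 and 0.07, above the −0.03 of all 39 markers. They lay below the 0.48 of the 16 markers, but those, unlike the lists, were picked by their wild-type level. The comparison therefore cannot decide on carry-over, which stays open as a source of the rise. For RNA quality, 11 germline members called without mutant replicate 2 were compared between the mutant arrays. Mutant replicate 2 differed from the wild type 1.01 times as much as mutant replicates 1 and 3 did (interval 0.815 to 1.21). The rise was thus also seen on the array without a raised 3' to 5' difference. This ratio has the limits given above for the lower calls, so it cannot decide on RNA quality. Derepression of germline genes in somatic cells of the mutant is a hypothesis that stays untested, as whole larvae do not show which cells express these genes, and a change in the number of germ cells was not tested.

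Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many as 2542 calls, and the highest of the others gave 0. With 10 splits the share cannot fall below 0.1, so they are too few to test chance.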

How the results depend on the processing

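Of the results for named genes under the alternatives fixed beforehand, 2002 kept their side of the threshold, 364 lost the call and 7 gained it. For gene lists these numbers were 746, 66 and 6, and 1 reversed. Turns of sign that left the side of the threshold unchanged are among the kept results. Those of lin-35 and of the meiotic median with median centring are examples. The 132 called named genes turned direction in 0 alternatives, and lin-35 was called in none. Under the alternatives chosen after seeing the data, 288 named gene results were the same, 143 were weaker and 1 gained a call. For most settings below the cause of the change was not tested.

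Leaving out 1 array gave 1002 to 2380 calls, 649 to 1173 higher, 353 to 1235 lower and 983 to 1788 at least 2-fold, with fewer samples in each fit. The lowest of each came without wild-type replicate 1. Without probe sets that can match several transcripts there were 1643 calls, 753 higher and 1122 at least 2-fold, from fewer probe sets tested. Ordinary unmoderated statistics gave 478 calls, 314 higher, 164 lower and 373 at least 2-fold, with 65.7% of calls higher. The floor at the 10th percentile gave 1552, 826, 726 and 1024 in that order. Median centring gave 2117 lower calls, and treat with a fold of 1.5 left 523 in place of 1734 changed at least 2-fold. With mutant replicates 1 and 3 out there were 768 calls, 583 higher, 185 lower and 768 at least 2-fold. With wild-type replicate 2 and mutant replicate 1 out 759 were lower, and with the 3' to 5' covariate 753 were lower. Median log2 differences reversed for ribosomal proteins with cyclic loess (0.18, adjusted p = 0.00092, range over alternatives 0.00092 to 0.782) and for the proteasome with mutant replicates 1 and 3 out (0.34, adjusted p = 0.000994, range 0.000994 to 0.948). The cause was not tested.

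Deviations of same-numbered arrays correlated at 0.0479, 0.0832 and 0.0731, and not every array correlated best with its own number. With so few arrays per genotype, these correlations cannot decide whether the replicate numbers pair the arrays, so pairing stays open. The replicate block gave 3063 calls in place of 2542. Signal over background limits dim probe sets, for which no detection calls were used.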

Other observations

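The tests of gene families by shared symbol were chosen after the data were seen. Genes of the mitochondrial ribosome leaned lower in lin-35(n745). Of 59 mitochondrial ribosomal protein genes 23 were called lower and 0 higher. The large subunit genes had a median log2 difference of −0.72 (13 of 34 lower, camera adjusted p = 3.77e-10 over 233 families) and the small subunit genes of −0.68 (10 of 25 lower, adjusted p = 1e-05), negative also under the 3 other scalings. With an estimated correlation the adjusted p was 0.918 for both, and 0 of the 34 families called with the preset correlation were called. The gene mrpl-2 was lower by −2.09 (SE 0.19, limma adjusted p = 0.00119), mrpl-18 by −1.74 (SE 0.18, adjusted p = 0.0019) and mrps-2 by −1.33 (SE 0.16, adjusted p = 0.00327). The counts of large and small subunit genes were 8 and 2 without wild-type replicate 1 and 9 and 3 without wild-type replicate 2. The small subunit count was 6 without mutant replicate 3. With mutant replicate 2 as the lone mutant array they were 2 and 1, while the medians were −0.81 and −0.67.

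Single genes of transport and of the response to infection, picked after their values were seen, rose strongly, while the detoxification and antimicrobial lists fixed beforehand were not called (camera adjusted p = 0.811 and 0.808). The ABC transporters pgp-5 and mrp-2 rose by 4.01 and 3.04 (SE 0.19 for mrp-2, limma adjusted p = 0.000312), and zip-2, a transcription factor that controls irg-1 during infection, rose by 2.31. Of 64 ugt genes 10 rose and 2 fell (median 0.22, camera adjusted p = 0.00515), whereas of 40 gst genes 12 fell and 0 rose (median −0.45, adjusted p = 0.00177), with adjusted p of 0.918 for both with an estimated correlation. Of 23 pals genes, a family with members induced by intracellular pathogens, 7 rose and 1 fell (median 1.09, adjusted p = 7.43e-05, and 0.918 with an estimated correlation), led by pals-6 at 3.24 (SE 0.40, limma adjusted p = 0.00399). The signs of these medians held under the 3 other scalings. Without wild-type replicate 1 there were 5 ugt genes and 3 pals genes higher and 6 gst genes lower. Without wild-type replicate 2, 3 pals genes were higher and 6 gst genes lower, and without wild-type replicate 3, 6 ugt genes were higher. Without mutant replicate 1, 11 pals genes were higher, without mutant replicate 2, 3 were, and without mutant replicate 3, 7 gst genes were lower. The lower ugt count was 0 without any 1 of the wild-type replicates and 1 without mutant replicate 2 or 3. With mutant replicate 2 as the lone mutant array, 5 ugt genes were higher (median 0.11) and 3 gst genes lower (median −0.30). The ugt median was 0.13 with the 3' to 5' covariate, and the gst median −0.25 without wild-type replicate 2. With the 3' to 5' covariate 8 gst genes were lower and 1 higher, and 11 pals genes were higher and 2 lower. The lower pals count was 0 without any 1 of the wild-type replicates and 2 without mutant replicate 1 or 3.

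Genes called higher lay next to each other more often than chance gives. Of 13606 pairs of adjacent measured genes, 109 had both members called higher where 48.2 were expected, a ratio of 2.26 that exceeded all 10000 permutations (permutation p = 1e-04, the smallest they can give). Probe sets that match more than 1 gene could produce this among duplicated genes. With probe sets marked as such in their identifiers left out, 57 pairs were observed against 21.1 expected, a ratio of 2.702. The 57 pairs lay above the largest count of the permutations, 40, so probe sets marked in this way are argued against as the cause. Whether the probe sets kept also bind similar neighbouring genes was not tested. Operons and regulation shared by neighbours were not tested and stay open. Runs of adjacent genes chosen after their values were seen include fbxa-163, fbxa-164, fbxa-165, fbxa-166 and fbxa-158, 5 genes higher by 1.13 to 2.29, and mis-12, Y47G6A.25, inx-22 and inx-21, 4 genes higher by up to 3.95. The insulin-like peptide genes ins-24, ins-30 and ins-26, neighbours of each other, were lower by −1.53 to −2.05, where for lower calls 85 pairs were observed against 56.3 expected (permutation p = 3e-04). The calls of ins-24 and ins-26 were not kept without each array, ins-24 being lost without wild-type replicate 1 (adjusted p = 0.0592) and mutant replicate 3 (0.0715). For ins-26 the call was lost without wild-type replicate 1 (0.138), wild-type replicate 2 (0.129), mutant replicate 1 (0.0847), mutant replicate 2 (0.0546) or mutant replicate 3 (0.138).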
